A study of Rattus norvegicus with 6 samples.

How the data were processed

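The series holds 6 libraries of the rat line RLE-6TN, 3 labelled normal saline and 3 labelled LPS at 5 µg/ml, both for 24 h in medium with 10% fetal bovine serum. Per the labels' protocols, ribosomal RNA was removed from total RNA with a commercial kit and libraries were built with a low-input RNA kit. The table deposited by the authors gives raw counts per Ensembl gene, per the file headers, for 14487 genes, all of them protein coding, each with at least 1 count over the 6 libraries. The aligner, the counting program, its use of strand, the genome build and the annotation release are not given in the sources used here, so no coordinates are given and genes that overlap or have near-identical copies are uncertain. The same table names 6 columns of normalized values, which were not used here. Gene symbols are those of the table; 380 rows share 179 symbols, and 27 rows have no symbol. The labels do not say whether the samples of a group were separate cultures, so p-values measure the spread between these samples, which may be technical. The titles of the LPS samples carry the same letters as those of the controls, NC, behind a prefix, Seq_, that the control titles lack. Groups were taken from the treatment label. The prefix divides the samples exactly as that label does, and its meaning is not given. Whatever it stands for cannot be told apart from treatment.

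Counts were tested with edgeR 4.0.16 in R 4.3.3, as its quasi-likelihood F test with TMM factors and filterByExpr (minimum count 10, minimum total 15), which kept 11830 genes and left out 2657. P-values were adjusted by Benjamini and Hochberg over all tested genes, with a threshold of 0.05; the 2-fold count also needed an absolute log2 fold change of 1. Standard errors are the absolute log2 fold change over the square root of the F statistic, and 95% intervals use the moderated degrees of freedom. Levels are counts per 1000000 (CPM) of TMM-scaled library size, as mean ± SD of 3 libraries. The biological coefficient of variation was 26.3%. At an unadjusted p under 0.05 there were 2233 genes, where 592 are expected by chance. Intervals do not cover PCR duplicates, as counts of reads without molecular identifiers are not independent molecules.

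The tests, groups, 24 gene lists and alternatives were chosen before the data were examined. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 24 lists. Of these, 6 passed with the preset correlation and 0 with an estimated one. Named genes were the 6 largest changes per direction among called genes with a mean of at least 1 CPM, no overlap between groups and a symbol that is not an identifier; up to 3 called members per list, or the most abundant member where none passed; and 17 fixed genes of surfactant, LPS response and lipid synthesis. Some of the genes this rule selects are not reported here. Other genes are named where the text says that they were chosen after their values were seen. Alternatives were DESeq2 1.42.0, limma-voom, median-of-ratios and upper-quartile scaling, no filter, a mean of at least 5 CPM, the replicate number as a block, mitochondrial and histone genes left out, and each library left out. Of the library measures, 6 were compared between groups by exact permutation tests, whose p cannot go below 0.1 with 3 against 3. Figures and these tests used Python 3.11.15, scipy 1.17.1 and matplotlib 3.10.9.

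No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom between them ran from 22.3 to 109. On simulated counts for the 11830 genes of LPS against control, edgeR recovered 4.5% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 84.8% of those changed 4-fold, with 7 false calls. DESeq2 recovered 11.9%, 64.2% and 87.9%, with 29 false calls, and limma-voom 4.5%, 52.2% and 83.3%, with 4. Camera called a simulated list raised 1.5-fold and 0 of 23 unchanged lists. The simulated genes were drawn independently, whereas the estimated correlation was 0.331 in the sterol list and 0.843 in mitochondrially encoded genes. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists of correlated genes.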

Results

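Transcript levels were measured in RLE-6TN, a cell line derived from rat alveolar type II cells, the lung cells that make and recycle pulmonary surfactant. Cultures had received normal saline (control, 3 libraries) or 5 µg/ml bacterial lipopolysaccharide (LPS, 3 libraries) for 24 h, and total RNA depleted of ribosomal RNA was sequenced. The study addressed how surfactant and lipid metabolism are disturbed in injured type II cells. Over 14487 protein-coding genes, the control libraries held 26611354, 27721564 and 27494041 counts and the LPS libraries 28874067, 28316331 and 28475225. Levels are given in counts per 1000000 (CPM), as mean ± SD with n = 3, control first and LPS second. The groups are named here as labelled, because genes that LPS is known to raise lay lower in the libraries labelled LPS.

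Of 21 surfactant and type II identity genes, 5 had enough counts to test, and the transcripts of the surfactant proteins, Sftpa1, Sftpb, Sftpc and Sftpd, were not analysed here. Lamp3, a lamellar body marker, had counts of 0, 0 and 0 in the control libraries and 0, 4 and 0 in the LPS libraries. Abca3, the lipid transporter of lamellar bodies, stood at 11.9 ± 2.87 CPM in control and 11.3 ± 0.726 CPM in LPS libraries (log2 fold change -0.08, SE 0.24, adjusted p = 0.892). Etv5, named after its values were seen, had 20.1 and 11.4 CPM and did not pass (adjusted p = 0.105). As a set the list did not pass camera (adjusted p = 0.117), but lay lower without LPS replicate 2 (adjusted p = 0.0126). Of the 5 tested genes, the largest change was that of Muc1, a gene near the floor, with 0.630 and 0.165 CPM. Its log2 fold change was -1.91 (SE 1.29, edgeR adjusted p = 0.445). Cebpa was also low, with 0.937 and 0.998 CPM. Both genes were named after their values were seen.

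In the comparison of LPS with control, 89 of 11830 tested genes differed at an adjusted p under 0.05 in edgeR's quasi-likelihood test, 33 higher and 56 lower in the libraries labelled LPS. Of these, 55 changed at least 2-fold, 17 upward and 38 downward. Fam180a rose most among named genes, from 3.55 ± 1.01 to 20.6 ± 4.83 CPM (log2 fold change 2.54, SE 0.29, adjusted p = 0.00487). Angptl4, an inhibitor of lipoprotein lipase, had only 7, 26 and 8 counts in the LPS libraries. It fell from 5.50 ± 2.21 to 0.483 ± 0.379 CPM (log2 fold change -3.50, SE 0.63, adjusted p = 0.0386). This call was lost without control replicate 1 or 2 or any 1 LPS replicate (adjusted p 0.0521 to 0.169). The number of calls rested on single libraries: it was 7 without LPS replicate 2, 18 without control replicate 2, 29 without LPS replicate 1 and 303 without control replicate 3. All 89 called genes had no overlap between the groups, as did 24.8% of all tested genes, against 10% by chance.

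Targets of NF-kB, the transcription factor through which LPS induces cytokines, were lower in the libraries labelled LPS. Of 35 tested members of this list, 13 fell and 0 rose (20 fell when adjusted over the list alone). Among members at an unadjusted p under 0.05, 21 were lower and 0 higher. DESeq2 called 20 lower and 0 higher, and limma-voom 11 lower and 0 higher. Zc3h12a, which encodes an RNase that degrades cytokine transcripts, fell from 121 ± 14.2 to 17.9 ± 1.96 CPM (log2 fold change -2.76, SE 0.16, adjusted p = 6.19e-05). The neutrophil chemokine Cxcl1 fell from 1390 ± 301 to 245.5 ± 13.9 CPM (log2 fold change -2.50, SE 0.17), and Nfkbia, the inhibitor that NF-kB itself induces, from 169.6 ± 23.7 to 39.1 ± 4.62 CPM (log2 fold change -2.12, SE 0.16). The monocyte chemokine Ccl2 fell from 2250 ± 516 to 790.3 ± 109.7 CPM, and the granulocyte growth factor Csf3 had a log2 fold change of -3.43 (SE 0.36). Il6 was low in both groups, at 2.53 ± 0.270 and 3.18 ± 2.12 CPM, and did not pass (adjusted p = 0.769). The list's median log2 fold change was -1.004 (camera adjusted p = 7.02e-14 with a preset correlation; adjusted p = 0.204 with an estimated correlation). Leaving out control replicate 2 left 5 of its genes called, and leaving out LPS replicate 2 left 4 and ended the call of Ccl2 (adjusted p = 0.0521). In these same LPS libraries fewer genes had a count, 12617 ± 119 against 13168 ± 101 in control.

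**Figure D1:**
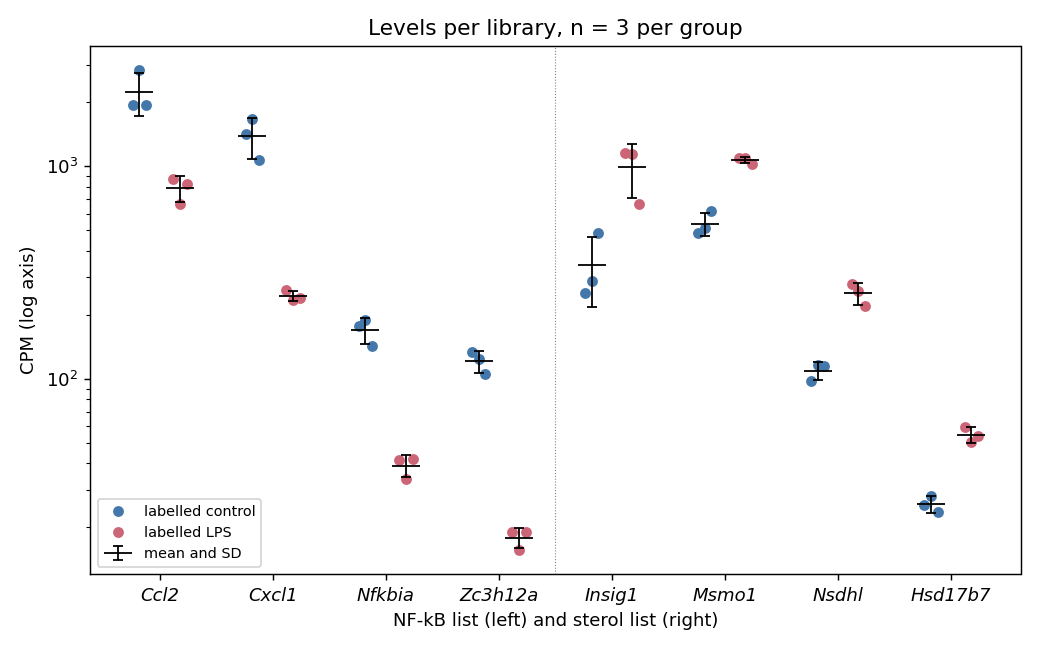
CPM on a log axis for 4 genes of the NF-kB list and 4 of the sterol list, in each of the 3 libraries per group, with bars for the mean and SD. Zc3h12a lay between 105 and 133 CPM in the libraries labelled control and between 15.6 and 19.1 CPM in those labelled LPS, while Msmo1 lay between 487 and 615 CPM and between 1029 and 1096 CPM.

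Genes of cholesterol synthesis and its regulation by SREBP2 moved the other way. Of 25 tested members, 12 rose and 0 fell in the libraries labelled LPS (20 rose when adjusted over the list alone). DESeq2 called 18 higher and 0 lower, and limma-voom 13 higher and 0 lower, with 20 higher and 0 lower at an unadjusted p under 0.05. The sterol enzymes Nsdhl, Msmo1 and Hsd17b7 rose. Nsdhl went from 109 ± 10.6 to 252.9 ± 29.6 CPM (log2 fold change 1.21, SE 0.15), Msmo1 from 538.6 ± 67.3 to 1073 ± 38.1 CPM (log2 fold change 0.99, SE 0.13) and Hsd17b7 from 25.7 ± 2.31 to 54.5 ± 4.68 CPM (log2 fold change 1.09, SE 0.15). Insig1, which holds SREBP precursors in the endoplasmic reticulum, rose from 342 ± 125 to 991 ± 281 CPM. The list's median log2 fold change was 0.80 (camera adjusted p = 7.02e-14; adjusted p = 0.344 with an estimated correlation). Its called genes numbered 0 without LPS replicate 2, 1 without LPS replicate 1 and 1 without control replicate 2. The call of Insig1 was also lost without control replicate 1 (adjusted p = 0.0972).

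Among 18 tested genes of fatty acid synthesis, 2 rose and 0 fell; adjusted over the list alone, 8 rose and 2 fell. DESeq2 called 6 higher and 1 lower, limma-voom 2 higher and 0 lower, and 10 were higher and 2 lower at an unadjusted p under 0.05. Acss2, which makes acetyl-CoA from acetate, rose from 39.5 ± 7.20 to 113.6 ± 31.6 CPM (log2 fold change 1.52, SE 0.23), and Acly, which makes it from citrate, from 640.3 ± 19.0 to 998.8 ± 38.6 CPM (log2 fold change 0.64, SE 0.12). Both calls were lost without control replicate 2, LPS replicate 1 or LPS replicate 2 (adjusted p 0.0813, 0.0956 and 0.0826 for Acss2 and 0.188, 0.179 and 0.193 for Acly). Fasn, fatty acid synthase, had 730.3 ± 59.1 and 786.8 ± 36.5 CPM (adjusted p = 0.665), and Srebf1, the gene of its activator SREBP1, had 63.8 ± 13.1 and 42.6 ± 5.34 CPM (log2 fold change -0.58, SE 0.18, adjusted p = 0.131). The list passed camera (adjusted p = 0.00163) and did not with an estimated correlation (adjusted p = 0.204).

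Phospholipids are the main lipid class of surfactant. Of 32 tested genes of their synthesis, 1 rose and 0 fell (2 and 0 when adjusted over the list alone). DESeq2 called 3 higher and 0 lower, limma-voom 1 higher and 0 lower, and 5 were higher and 3 lower at an unadjusted p under 0.05. The edgeR call was the choline transporter-like gene Slc44a2, from 81.8 ± 7.35 to 137.1 ± 13.1 CPM (adjusted p = 0.0441). Its call was lost without control replicate 1 or 2 or LPS replicate 1 or 2 (adjusted p 0.0769, 0.211, 0.186 and 0.193). Pcyt1a, which encodes the rate-limiting enzyme of phosphatidylcholine synthesis, had a log2 fold change of -0.06 (95% interval -0.35 to 0.22). Lpcat1, which remodels surfactant phosphatidylcholine, had 106 ± 7.99 and 82.6 ± 9.92 CPM (log2 fold change -0.36, SE 0.15, adjusted p = 0.219). Of the 5 tested surfactant and type II genes, 0 passed in edgeR and 0 in limma-voom; 1 was lower in DESeq2, 2 were lower at an unadjusted p under 0.05, and 1 was lower when adjusted over the list alone. Phospholipases and sphingolipid enzymes had 0 of 25 called by edgeR and 0 by limma-voom, 1 higher by DESeq2, 1 higher when adjusted over the list alone, and 2 at an unadjusted p under 0.05. Asah1, acid ceramidase, had a log2 fold change of 0.66 (SE 0.14, adjusted p = 0.0652, and 0.0374 without control replicate 3). For lipid uptake, storage and efflux the numbers were 0 of 24 by edgeR, 0 by limma-voom, 1 lower by DESeq2, 0 adjusted over the list alone and 6 unadjusted, and Npc2, a lysosomal cholesterol carrier, had a log2 fold change of 0.29 (SE 0.14). Fatty acid oxidation and PPAR targets had 1 of 24 lower, Angptl4, and 0 higher, whether adjusted over all genes or over the list alone. DESeq2 called 0 higher and 1 lower and limma-voom 0, and 1 was higher and 2 lower at an unadjusted p under 0.05.

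The receptor and signalling genes of the LPS pathway showed no call in edgeR. Of 19 tested members, 0 passed there or in limma-voom, 0 when adjusted over the list alone, 2 were lower in DESeq2 and 4 were lower at an unadjusted p under 0.05. Tlr4, the LPS receptor, had 27.5 ± 13.5 and 36.9 ± 8.93 CPM (log2 fold change 0.42, 95% interval -0.32 to 1.16), and its co-receptor Cd14 had 38.5 ± 12.0 and 29.9 ± 5.28 CPM (log2 fold change -0.36, SE 0.24). Irak3, an inhibitor of the same pathway, had a log2 fold change of -0.76 (SE 0.25, adjusted p = 0.146). In the interferon and antigen presentation list 0 of 31 passed in edgeR and 0 in limma-voom, 0 when adjusted over the list alone, 1 was higher and 1 lower in DESeq2, and 7 had an unadjusted p under 0.05. B2m had a log2 fold change of 0.15 (SE 0.11).

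Further genes with large changes came from several functions. Bdkrb1, a bradykinin receptor, fell from 29.6 ± 5.52 to 5.20 ± 1.13 CPM (log2 fold change -2.51, SE 0.24), and Nox1, a superoxide-generating oxidase, from 237.4 ± 95.1 to 47.6 ± 14.6 CPM (log2 fold change -2.32, SE 0.29). Tmcc3 rose from 11.7 ± 2.39 to 30.9 ± 3.69 CPM. The call of Nox1 was lost without LPS replicate 1 or 2 (adjusted p 0.0564 and 0.0521), and that of Tmcc3 without control replicate 2, LPS replicate 1 or LPS replicate 2 (adjusted p 0.059, 0.0956 and 0.0863). Of 22 tested genes of glycolysis and hypoxia, 1 rose and 1 fell (5 and 1 when adjusted over the list alone). DESeq2 called 3 higher and 1 lower, limma-voom 0 higher and 1 lower, and 8 were higher and 1 lower at an unadjusted p under 0.05. The edgeR calls were Bnip3, a mitophagy receptor, with a log2 fold change of 1.33 (SE 0.25), and Egln3, an oxygen-sensing hydroxylase, with -1.02 (SE 0.20); limma-voom did not call Bnip3 (adjusted p = 0.0524). That list had a camera adjusted p of 0.0255, and an adjusted p of 0.667 with an estimated correlation. The camera value was 0.153 without control replicate 2, 0.166 without control replicate 3 and 0.078 without LPS replicate 1. Of 23 mesenchymal and matrix genes, 1 fell, Postn, from 31.4 ± 15.3 to 7.04 ± 1.44 CPM, and 0 rose; adjusted over the list alone, 6 fell and 1 rose. In DESeq2 6 were lower and 0 higher, in limma-voom 0 passed, and 7 were lower and 1 higher at an unadjusted p under 0.05. This list's camera adjusted p was 0.109, and 0.0335 without control replicate 3. The calls of Bnip3, Egln3 and Postn were each lost without control replicate 1 (adjusted p 0.118, 0.0769 and 0.0972), control replicate 2 (0.188, 0.188 and 0.161), LPS replicate 1 (0.174, 0.202 and 0.173) or LPS replicate 2 (0.17, 0.193 and 0.131).

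Cytosolic ribosomal protein genes had a median log2 fold change of 0.22 (camera adjusted p = 4.11e-05; adjusted p = 0.667 with an estimated correlation). Of 89 tested rows, 2 rose and 0 fell (3 and 0 when adjusted over the list alone). DESeq2 called 10 higher and 0 lower, limma-voom 3 higher and 0 lower, and 17 were higher and 1 lower at an unadjusted p under 0.05. The groups overlapped: as a share of counts these genes took 4.60% in control replicate 1 and 3.43% and 3.56% in the other control libraries, against 4.27% to 4.56% in the LPS libraries (exact two-sided permutation p = 0.4). The camera adjusted p ran from 1.84e-18 without control replicate 1 to 0.0443 without control replicate 3. Both called rows are uncertain because ribosomal protein genes have near-identical copies. One row named Rps27a (ENSRNOG00000034246) rose from 127.7 ± 21.2 to 520 ± 69.3 CPM (log2 fold change 2.02, SE 0.17), while the other (ENSRNOG00000004426) had 856 ± 216 and 677 ± 170 CPM. Summed, they did not pass (log2 fold change 0.28, adjusted p = 0.389). Rpl5l1 had a log2 fold change of 0.74 (SE 0.14). Its call was lost without control replicate 1 or 2 or LPS replicate 1 or 2 (adjusted p 0.0784, 0.188, 0.194 and 0.193). Mitochondrially encoded genes had a median log2 fold change of 0.27 (camera adjusted p = 0.0221; adjusted p = 0.667 with an estimated correlation; adjusted p = 0.364 without control replicate 1 and 0.0505 without LPS replicate 2). Of these 11 genes, edgeR and limma-voom called 0, DESeq2 called 1 higher, 1 rose when adjusted over the list alone, and 3 had an unadjusted p under 0.05. Mt-co1 had 24360 ± 5027 and 30500 ± 1327 CPM. As a share of counts, mitochondrial genes took 5.13 ± 1.14% in control and 6.26 ± 0.411% in LPS libraries (exact two-sided permutation p = 0.2, where 0.1 is the smallest possible), and control replicate 1 had the lowest share, 3.93%.

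**Figure D2:**
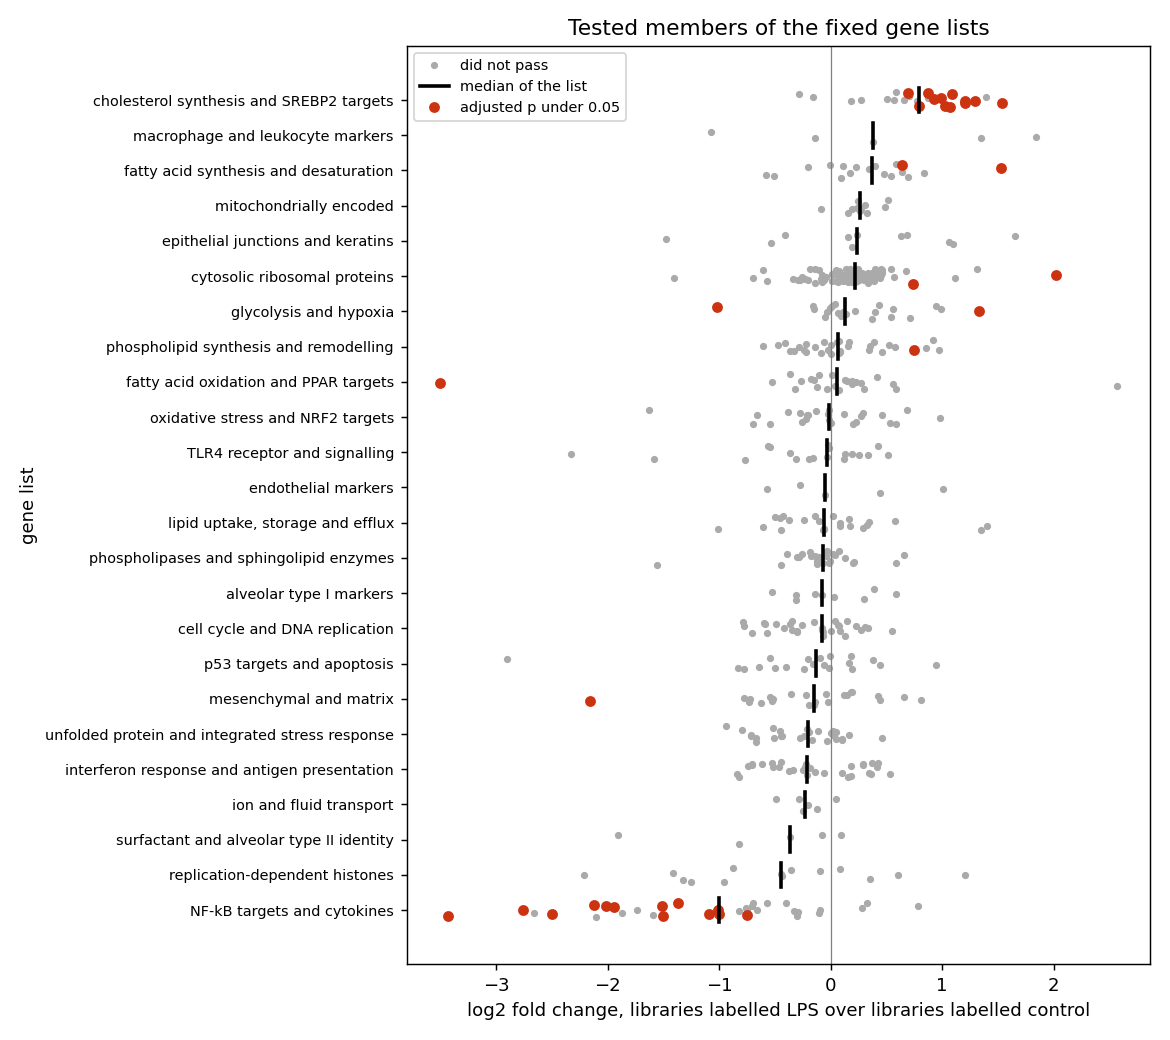
Log2 fold change of each tested member of the 24 fixed lists, libraries labelled LPS over those labelled control, with red points for adjusted p under 0.05, grey points for the rest and a black bar at each list's median. The NF-kB list has its median at -1.004 with 13 red points below 0, and the sterol list at 0.80 with 12 red points above 0.

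For the remaining lists edgeR and limma-voom called 0 genes. In cell cycle and DNA replication, 8 of 32 genes were lower at an unadjusted p under 0.05, 3 in DESeq2 and 1 when adjusted over the list alone, and Mki67 had a log2 fold change of -0.07 (SE 0.17). The list's camera adjusted p was 0.143, and 0.0413 without LPS replicate 3. In the unfolded protein and integrated stress response, 9 of 28 had an unadjusted p under 0.05, 4 were lower in DESeq2 and 1 was lower when adjusted over the list alone. Hsp90b1 had a log2 fold change of 0.10. The list's camera adjusted p was 0.0913, with 0.0443 without control replicate 3 and 0.0111 without LPS replicate 2. Oxidative stress and NRF2 targets had 8 of 26 unadjusted, 4 higher and 1 lower both in DESeq2 and when adjusted over the list alone, and Fth1, ferritin heavy chain, had a log2 fold change of 0.53 (SE 0.15, adjusted p = 0.114, and 0.049 without control replicate 3). Among p53 targets and apoptosis genes 6 of 20 passed unadjusted, 1 was higher and 3 lower in DESeq2, and 0 passed when adjusted over the list alone. Ccng1 had a log2 fold change of 0.19. Ion and fluid transport had 1 of 6 unadjusted, 0 in DESeq2 and 1 lower when adjusted over the list alone.

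Markers of other cells gave no call in edgeR or limma-voom apart from Postn in edgeR. Of 9 alveolar type I markers 3 passed unadjusted, 1 was higher in DESeq2 and 0 passed when adjusted over the list alone. Cav1 had 1003 ± 91.4 and 1023 ± 44.5 CPM. Of 11 epithelial junction and keratin genes 3 passed unadjusted, 1 was higher and 1 lower both in DESeq2 and when adjusted over the list alone, and Tjp1 had a log2 fold change of 0.16. Of 5 endothelial markers 1 passed unadjusted, 0 in DESeq2 and 0 when adjusted over the list alone, with Eng at a log2 fold change of -0.27. Of 5 macrophage and leukocyte markers 0 passed unadjusted, in DESeq2 or when adjusted over the list alone. The most abundant, Itgax, had 5.60 ± 1.72 and 7.29 ± 3.52 CPM. Replication-dependent histone genes had 1 of 14 unadjusted, 0 in DESeq2 and 0 when adjusted over the list alone, and Hist1h4b (ENSRNOG00000030142) had a log2 fold change of 0.09. The list's median was -0.44, with 10 of 14 members below 0. Its camera adjusted p was 0.225, and 0.00793 with no filter on low counts.

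**Figure D3:**
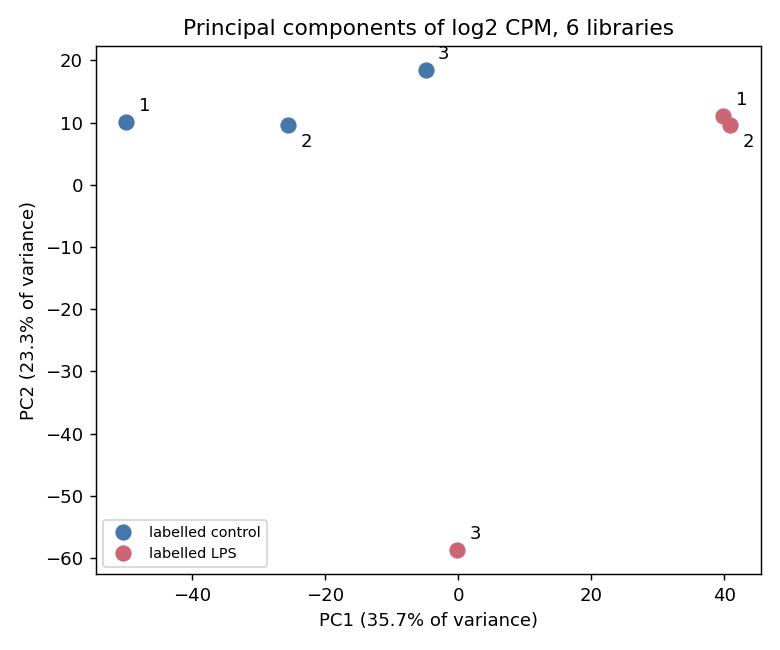
First and second principal components of log2 CPM for the 6 libraries, numbered by replicate, with 35.7% and 23.3% of the variance. On the first component control replicate 1 lies at -50.0 and LPS replicates 1 and 2 at 39.9 and 40.9, while LPS replicate 3, at -0.18, lies near control replicate 3, at -4.94, and stands apart from the other 5 libraries on the second at -58.8.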

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

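The summed-symbol setting and the removal of control replicate 1 together with LPS replicate 3 were chosen after seeing the data; the other settings were planned. With symbols summed, directions of all called genes were not compared; in the other settings each of the 89 kept its direction where it was tested, but the number of calls did not hold, and the cause was not tested except where fewer libraries or other genes entered. For all genes and for 2-fold changes the calls were 736 and 201 with DESeq2, 184 and 99 with no filter, 463 and 122 without both of those libraries, and 7 to 303 and 7 to 157 over the single libraries left out. With the replicate block they were 10 and 10, all 10 among the 89. Whether the numbers pair the samples is not known. Deviations of same-numbered libraries correlated at -0.049, 0.012 and -0.229, and 0 of 3 numbers matched best with their own. With 3 libraries per group, these values give no sign of pairing but cannot exclude it. The lower NF-kB genes numbered 20 with DESeq2, 4 with the replicate block and 4 to 17 over single libraries left out. The higher sterol genes numbered 0 with the replicate block, 19 without both libraries and 0 to 16 over single libraries left out. With limma-voom, median-of-ratios or upper-quartile scaling, a mean of at least 5 CPM, and mitochondrial and histone genes left out, calls ran from 87 to 111. The number of lists passing, 6 in the main test, was 0 with an estimated correlation and 17 with fry in either direction. It was 4 with fry in one direction and 5 to 7 over single libraries left out. Those 4 include epithelial junctions and keratins (higher, fry adjusted p = 0.0199), which is not among the 6 (camera adjusted p = 0.143). The replicate block changed no list call.

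Of the 23 named genes called, 53 of 161 values with libraries left out and 20 of 206 others lost the call, and 0 turned. Among the named genes not called, some directions turned, none past the test: Cav1 (highest 0.105 with 1 library left out) was -0.025 without control replicate 1, -0.007 without LPS replicate 3 and -0.062 without both libraries; Hist1h4b (highest 0.265) was -0.029 without control replicate 2, -0.063 without LPS replicate 3 and -0.036 with symbols summed. Mki67 (lowest -0.224) was 0.111 and Abca3 (lowest -0.255) 0.084 without control replicate 3, Itgax (highest 0.663) -0.079 and Il6 (highest 0.658) -0.346 without LPS replicate 1, and Ccng1 -0.087 without both libraries. The alternatives planned for normalized values (pseudocounts, no trend, quantile scaling) do not apply to counts and were not run. Depth of 26611354 counts or more left 2657 genes below the filter, and changes of 1.5-fold were mostly out of reach of 3 libraries per group.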

Other observations

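Most tests below were chosen only after the results were seen: those of a mislabelled library, scaling, NF-kB inhibitors, leukocytes, the Rps27a rows, the detection of genes and the pathways; the test of exchanged labels and the splits of the samples were written before. The tests of scaling, inhibitors and leukocytes were redefined after first versions had been run and their values seen, that of inhibitors 3 times; the first leukocyte test, on all libraries, and the second inhibitor test, on Irak3 alone, had left those explanations open.

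Several called genes outside the named groups were lower in the libraries labelled LPS; they were picked after their values were seen. The amino acid transporters Slc7a5, Slc1a5 and Slc7a1 had log2 fold changes of -1.39 (SE 0.21, adjusted p = 0.0147), -1.16 (adjusted p = 0.0147) and -0.86 (adjusted p = 0.0414). Ptx3, a soluble pattern recognition protein, fell from 2784 ± 260 to 1149 ± 176 CPM, the matrix protein gene Tnc from 2681 ± 797 to 1023 ± 110.3 CPM, and Timp1, a metalloproteinase inhibitor, from 252.1 ± 108.5 to 87.2 ± 10.7 CPM. Among 267 pathways of the deposited annotation, 10 passed camera with the preset correlation, 5 upward and 5 downward, and 0 with an estimated correlation. Steroid biosynthesis lay higher, with 8 of 18 genes called. The pathways nearest to the NF-kB list did not pass: NF-kappa B signaling had an adjusted p of 0.345 (3 of 63 genes called, all lower, median log2 fold change -0.055), TNF signaling 0.199 (7 of 86, all lower), cytokine-cytokine receptor interaction 0.244 (5 of 86, all lower) and Toll-like receptor signaling 0.825 (2 of 63, both lower). DNA replication lay lower (median log2 fold change -0.36, adjusted p = 0.0125; adjusted p = 0.969 with an estimated correlation); edgeR called 0 of its 34 genes, and 14 were lower at an unadjusted p under 0.05. The other downward pathways were type I diabetes mellitus and allograft rejection (camera adjusted p = 0.0125 each), graft-versus-host disease (0.0177) and autoimmune thyroid disease (0.0181). In these, edgeR called 0 genes, and 11, 9, 9 and 9 were lower and 0 higher at an unadjusted p under 0.05. The pathway of antigen processing and presentation did not pass (camera adjusted p = 0.422).

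The NF-kB list was lower and the sterol list higher in the libraries labelled LPS, the reverse of what LPS is known to do to NF-kB targets. One mislabelled library is argued against on these lists alone. The groups stood apart by 0.936 and 0.361 on the log2 scale (SD within groups 0.102 and 0.18). Both lists were singled out because they differed between the groups as labelled. Across all genes, LPS replicate 3 correlated more with control replicates 2 and 3 (r = 0.961 and 0.959) than with LPS replicates 1 and 2 (0.953 and 0.954). Scaling is argued against by the sterol list's mean log2 CPM minus that of the NF-kB list, which a factor per library cannot move. This difference was higher in each LPS library than in each control library by at least 1.501 (SD within groups 0.19). Leukocytes in the control libraries are argued against only by low levels of the markers analysed, and 10 of 19 listed markers were not analysed here. The highest level there was 7.586 CPM, for Itgax, which had a higher mean in the LPS libraries (up to 11.33 CPM). Cd68 and Cd74 stayed at or below 1.109 CPM in each library. Directions differed between markers. Cd68 had 0.723, 1.109 and 0.962 CPM in control and 0.034, 0.354 and 0.939 CPM in LPS libraries. Aif1 had 0.913, 0.215 and 0.107 CPM in control and 1.986, 0.743 and 1.697 CPM in LPS libraries. Exchanged treatment labels may account for the pattern and cannot be told apart from an effect of LPS, which was not tested: 98 genes annotated to lipopolysaccharide outside the lists had a median log2 fold change of -0.102 and did not pass as a set (camera adjusted p = 0.197, the set being tested alone). Higher transcripts of an NF-kB inhibitor at 24 h, with 1 rule for each of 6 genes, are argued against only for Zc3h12a (log2 fold change -2.76), Nfkbia (-2.119), Tnfaip3 (-1.945) and Tnip1 (-1.009), called lower, although Tnfaip3 was so in only 11 of 16 alternatives and Tnip1 in 13, and stay open for Irak3 (-0.764, adjusted p = 0.146, and 0.0311 in DESeq2) and Nfkbie (-0.097); 5 of the 6, all but Irak3, are in the NF-kB list, so their fall is part of the pattern and does not tell what lowered it, and an earlier rise or inhibition by protein was not tested.

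One of 2 rows named Rps27a rose 4.07-fold. Reads moving between the 2 rows could produce this, and then the other row should lose about what this one gained; it fell by 45.6% of the gain, a difference that did not pass (adjusted p = 0.412), while the sums overlapped between groups. A fall of at least 75% was asked for, a limit set after the value was seen. Reads shared between copies therefore cannot be told apart from a rise of this row, and no biological explanation was tested.

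Fewer genes had a count in the libraries labelled LPS, and 118 genes had counts in all 3 control libraries with at most 1 count over the LPS libraries, against 16 the other way. Background reads in the control libraries are argued against only for the 1007 genes with a mean of 3 to 10 counts. Over these, the ratio of LPS to control totals was 1.036, while that of detected genes was 0.777. Genes with a lower mean, where such reads could also lie, were not tested. Fewer distinct molecules behind the LPS counts may be the cause, but the test made of it cannot decide. Among the 1007 genes, 870 had a count in both groups. Over these 870, the median variance-to-mean ratio was higher in LPS by 3.734 (95% bootstrap interval 3.083 to 4.381). Fewer detected genes at like totals raise this ratio by themselves, so it restates the pattern. More uneven cultures would give the same value, and an effect of LPS stays open, untested.

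With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The labelled split gave 89 genes, 55 of them 2-fold, and the highest other split 11 and 11, so 1 split reached each count. For the lists the labelled split gave 6 and the highest other 7, so 2 splits reached as many; the other 9 splits called 0 genes of the NF-kB list and 0 of the sterol list. Camera with the preset correlation passed the NF-kB list in 5 of those 9 splits (lowest adjusted p = 0.000128) and the sterol list in 5 (lowest adjusted p = 6.5e-05). Each of those 9 splits mixes both labels unevenly in its groups, so part of the labelled difference stays in it. The mixing also widens the spread within groups, which by itself makes gene calls fewer. Neither the camera passes nor the 0 calls therefore show what groupings unrelated to the labels would give.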
